A study of Homo sapiens with 9 samples.

How the data were processed

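Total RNA from A549 cells was isolated with a phenol reagent (TRIZOL), cleaned on RNeasy columns and labelled as biotinylated cRNA, per the labels' protocols. Each of 9 samples was read on an Affymetrix oligonucleotide array with 54675 probe sets. The deposited values are log2 expression levels made with RMA, per the submitters' processing notes; the version of that software and the background and summary settings are not given in the sources used here. The values ran from 3.60 to 15.06, with no missing value and no further scaling in the main setting. RMA is a method that includes normalization between arrays. Detection calls, scan dates and scanner files were not used here, so the level of dim probe sets has no background test, and no batch of scanning or labelling could be examined. All 9 columns of the table were matched to samples by the accession in the column name, and 0 columns were left unused.

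Samples were grouped by their titles into mock, NS siRNA and Nrf2 siRNA, 3 biological replicates each. The 62 control probe sets stayed out of the tests. Of the rest, 41091 carried exactly 1 gene in the annotation table given for the array, 1801 carried several genes and 11721 were unnamed here. Symbols were updated through Entrez identifiers with a RefSeq gene table of GRCh38.p14, which matched 41037 of the 41091; the other 54 kept their file name. No coordinates are printed, since the values name no genome build. Where a gene had several probe sets (10523 genes), the one with the highest mean over the 9 arrays stood for it, which left 19775 genes. Some genes are not reported here.

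All comparisons came from 1 linear model on the log2 values over the 9 arrays, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings), with 3 group means and 6 residual degrees of freedom; the prior added 6.12. P values were two-sided and adjusted by Benjamini-Hochberg over the 19775 genes, with a threshold of 0.05, and a count at 2-fold or more is given beside each total. The contrasts were Nrf2 siRNA against NS siRNA, Nrf2 siRNA against mock, NS siRNA against mock, and Nrf2 siRNA against the mean of both controls. An SD is over 3 arrays; an SE is the model's. A fold is 2 to the power of the log2 difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

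Before the data were examined, 32 gene lists were fixed, covering NRF2 regulators, glutathione, thioredoxin, quinone and aldehyde enzymes, conjugating enzymes, ABC transporters, NADPH, heme and iron, purine and one-carbon synthesis, ATF4 targets, the unfolded protein response, the proteasome, mitosis, DNA replication, p53, interferon, NF-kB, cholesterol, fatty acid synthesis and oxidation, glycolysis, respiration, hypoxia, epithelial, mesenchymal, autophagy, ribosome, RNA interference, fibroblast, immune, endothelial and lung markers. Of their 636 entries 574 were measured. Each list with 5 or more measured genes was tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list moves on balance one way without comparing it with other genes. Members past the threshold were also counted adjusted over the list alone.

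The genes named were set by rule: NFE2L2; the 12 largest falls and 12 largest rises against NS siRNA among genes called with the same sign against both controls whose 3 Nrf2 siRNA arrays lay beyond the 6 control arrays; up to 4 members of each list with the smallest adjusted p against NS siRNA; the 10 largest changes each way of NS siRNA against mock; and the 5 largest each way of Nrf2 siRNA against mock. Clone names, open reading frames and sex-linked markers were skipped. The rule gave 155 different genes. AKR1B10, AKR1C1, AKR1C2, NQO1, EPCAM, CDH1, BACH1, COL1A2, DCN and single genes in the closing section were added from the same lists after their values were seen.

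The alternatives tried were equal array medians, quantile normalization of the deposited values, a filter for genes above the median level of all probe sets, the mean of a gene's probe sets, the probe set with the largest interquartile range, each probe set on its own, an eBayes trend with robust variances, a fit on the compared groups alone, the replicate number as a block, leaving out each array in turn, a threshold of 0.01, and an unmoderated test. The fit was tested on simulated arrays with the real means and variances and 200 of 19775 genes changed in Nrf2 siRNA against NS siRNA: it recovered 100% of the genes changed by 2-fold, 100% of those changed by 1.41-fold and 72.5% of those changed by 1.19-fold, with 9 calls among unchanged genes. The simulated genes were independent of each other. Camera recovered the 1 shifted list there, which shows that the code runs and nothing about false calls among correlated genes.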

Results

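A549 cells, an established human lung adenocarcinoma line, were transfected with an siRNA against NRF2 (gene symbol NFE2L2, the transcription factor of the antioxidant response), with a non-targeting siRNA (NS siRNA), or with the transfection reagent alone (mock). Each group held 3 biological replicates, each on its own array, which made 9 arrays. Both siRNAs were used at 25 nM and RNA was taken 96 h after transfection. The purpose named for the series was to identify the genes that NRF2 regulates in these cells. Every array gave 54675 log2 expression values, and the array medians lay between 7.51 and 7.57. The number of arrays limits the precision: the median standard deviation between replicates was 0.0687 on the log2 scale. Arrays of the same group correlated at r = 0.9979 to 0.9987 across probe sets and arrays of different groups at 0.984 to 0.9937; probe sets are not independent replicates. The signal ratio between the 3' and 5' ends of the ACTB control transcript, a measure of RNA integrity, was -0.085 ± 0.017 (SD, n = 3, log2) in mock, -0.071 ± 0.011 in NS siRNA and -0.091 ± 0.046 in Nrf2 siRNA. The GAPDH ratio was 0.015 in mock, 0.018 in NS siRNA and 0.017 in Nrf2 siRNA. With 3 against 3 arrays the smallest possible p of a two-sided exact permutation test is 0.1, so that test could not pass 0.05, and whether the ratios differ is left open.

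The siRNA target came first. NFE2L2 stood at 11.99 ± 0.08 (SD, n = 3, log2) in mock, 12.09 ± 0.06 in NS siRNA and 10.25 ± 0.11 in Nrf2 siRNA. Single arrays ranged from 10.12 to 10.32 after Nrf2 siRNA and from 11.92 to 12.15 in the 6 controls. The level left was 27.9% of that in NS siRNA and 30.0% of that in mock (adjusted p = 1.92e-10 and 6.07e-10). NS siRNA and mock differed in NFE2L2 by 0.10 ± 0.06 (SE), which did not pass the test (adjusted p = 0.248). Of the 2 other NFE2L2 probe sets, the one at 8.64 in NS siRNA put the remaining level at 45.2%. The dimmer one, at 7.66 in NS siRNA, differed by -0.11 ± 0.06 and did not pass (adjusted p = 0.172, here adjusted over the 41091 probe sets with exactly 1 gene).

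**Figure D1:**
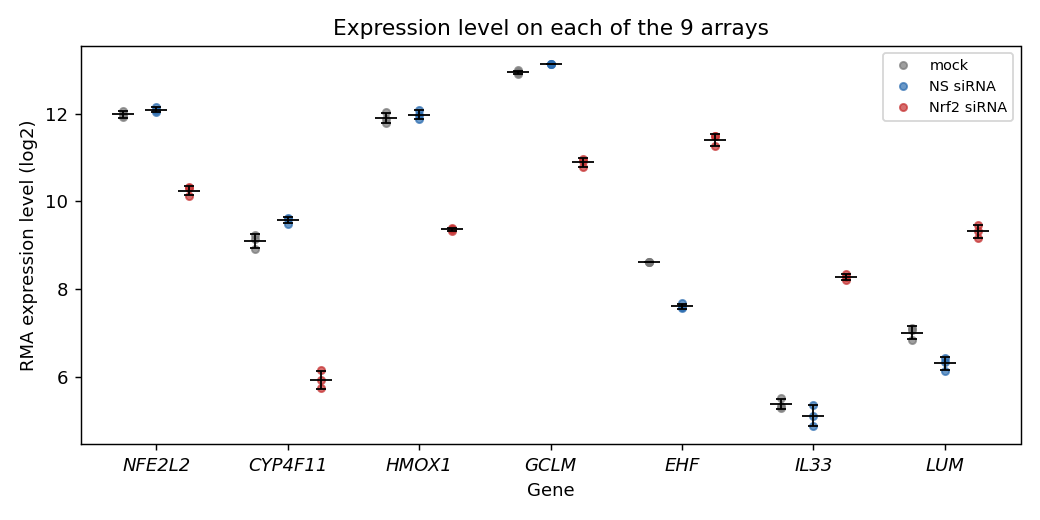
Expression level (RMA, log2) of 7 genes on each of the 9 arrays, with 1 point per array and the mean and standard deviation of each group of 3 in black. NFE2L2, CYP4F11, HMOX1 and GCLM lay lower on the 3 Nrf2 siRNA arrays than on the 6 control arrays, and EHF, IL33 and LUM lay higher; NFE2L2 averaged 10.25 after Nrf2 siRNA against 12.09 after NS siRNA.

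The main comparison, Nrf2 siRNA against NS siRNA, asked which transcripts differ after the Nrf2 siRNA. The series has no rescue and no other Nrf2 siRNA group. An effect of NRF2 loss therefore cannot be told apart from an off-target effect of that siRNA or from separate handling of its cultures. Enzymes of detoxification and glutathione synthesis were among the largest falls. CYP4F11, a cytochrome P450, fell 12.4-fold, from 9.57 ± 0.07 (SD, n = 3, log2) to 5.94 ± 0.21. ALDH3A1, an aldehyde dehydrogenase, fell 6.37-fold, HMOX1, the heme-degrading oxygenase, fell 6.10-fold, and PTGR1, a prostaglandin reductase, fell 5.72-fold. The catalytic and modifier subunits of glutamate-cysteine ligase, the rate-limiting enzyme of glutathione synthesis, fell 4.66-fold (GCLC) and 4.72-fold (GCLM). In the other direction, EHF, an epithelial ETS transcription factor, rose 13.8-fold, from 7.62 ± 0.06 to 11.41 ± 0.13, and the cytokine IL33 rose 8.95-fold. CYP4F11 after Nrf2 siRNA and IL33 in the controls (5.12 in NS siRNA) lay below the array medians, where a fold can be understated.

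The other genes among the 12 largest falls that were shared with the mock comparison were BCL2A1, an anti-apoptotic BCL2 relative (-3.11 ± 0.11 SE, log2), the protease-activated receptor F2RL2 (-2.78 ± 0.05), the pseudogene transcript NMRAL2P (-2.75 ± 0.06), the complexin CPLX2 (-2.59 ± 0.08), TRIM16 (-2.35 ± 0.06) and the pirin gene PIR (-2.24 ± 0.05). The 12 largest rises held RARRES1 (3.33 ± 0.08), the desaturase SCD5 (3.27 ± 0.06), RASGEF1A (3.17 ± 0.07), SYTL5 (3.17 ± 0.10), TOX3 (3.13), the matrix genes SPARC (3.06) and LUM (3.01), the phospholipase PLAAT3 (3.01), TMEM45A (2.83) and the RAS-family gene DIRAS3 (2.81). The largest adjusted p among the 24 was 1.93e-09 (TMEM45A). For SCD5, 3 of 4 probe sets changed the same way; for the other named genes of this group every probe set did. All 12 rises were smaller against mock, although for IL33 the 2 controls did not differ past the threshold (-0.26 ± 0.10 SE, limma adjusted p = 0.0619). The 12 were ranked by their size against NS siRNA, which by itself favours smaller values against mock. After NS siRNA, SCD5 stood at -2.68 and TMEM45A at -2.20 relative to mock (log2), and they rose by 0.58 and 0.63 against mock. PLAAT3 rose 8.04-fold against NS siRNA and 2.70-fold against mock, RARRES1 10.1-fold and 3.82-fold, DIRAS3 7.02-fold and 3.14-fold, SPARC 8.35-fold and 4.03-fold, EHF 13.8-fold and 6.86-fold, RASGEF1A 9.01-fold and 5.51-fold, and LUM 8.06-fold and 4.95-fold. SCD5, RASGEF1A, SYTL5, TOX3, LUM and TMEM45A in NS siRNA, and BCL2A1 and NMRAL2P after Nrf2 siRNA, also lay below the array medians, so their folds and ranks are uncertain. Likewise BCL2A1 was 1.66 higher in NS siRNA than in mock and fell by 1.45 against mock.

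Over all genes, 9422 of 19775 passed the threshold, 4156 higher and 5266 lower after Nrf2 siRNA, and 559 differed by 2-fold or more, 418 higher and 141 lower. The balance of directions depends on the scaling: 4340 were higher and 4372 lower with equal array medians, and 3916 and 5715 with quantile normalization. At adjusted p below 0.01 in the main setting, 3527 were higher and 3509 lower. Most called changes were small: 80.0% of them were below 1.5-fold, with a median size of 1.24-fold.

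Of 22 measured genes of quinone, carbonyl and aldehyde metabolism 17 fell and 2 rose, 17 and 2 also when adjusted over the list alone. Beside CYP4F11, PTGR1 and PIR, the carbonyl reductase CBR3 fell by 1.34, AKR1B10 by 1.42, AKR1C1 by 1.06 and NQO1, the quinone reductase, by 0.88. The list passed the camera test (adjusted p = 2.26e-08; adjusted p = 0.207 with an estimated correlation). AKR1C1 and AKR1C2 are near-identical in sequence, so their probe sets may read each other's transcripts, and the values of that family are uncertain. Of 16 glutathione genes 10 fell and 3 rose, 10 and 3 adjusted over the list alone. SLC7A11, the cystine importer, was at -2.01 and the peroxidase GPX2 at -1.39 (adjusted p = 0.00368; adjusted p = 0.319 with an estimated correlation). Of 11 thioredoxin and peroxiredoxin genes 7 fell and 0 rose, 7 and 0 adjusted over the list alone. SRXN1, sulfiredoxin, was at -1.95, the thioredoxin reductase TXNRD1 at -1.72 and TXN at -0.94 (adjusted p = 0.00127; adjusted p = 0.278 with an estimated correlation). For TXNRD1 1 of 2 probe sets changed that way.

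Of 12 heme and iron genes 11 fell and 1 rose, 11 and 1 adjusted over the list alone. HMOX1, the transferrin receptor TFRC (-1.15) and the iron transporter SLC11A2 (-1.01, 3 of 5 probe sets with that sign) fell, with adjusted p = 9.89e-05 for the list and adjusted p = 0.207 with an estimated correlation. Of 9 ABC efflux transporters 6 fell and 0 rose, 6 and 0 adjusted over the list alone. ABCG2 was at -1.50, ABCC2 at -1.37 and ABCC1 at -0.88 (adjusted p = 0.0238; adjusted p = 0.319 with an estimated correlation). The pentose phosphate and NADPH genes ME1 (-1.59), TALDO1 (-1.43), PGD (-0.74) and TKT (-0.69) fell. In that list 9 of 14 members fell and 3 rose, over all genes and adjusted over the list alone, but the list did not pass (adjusted p = 0.0536; adjusted p = 0.355 with an estimated correlation). It passed in 5 of 16 alternative settings: without NS siRNA replicate 3 (adjusted p = 0.0334), without Nrf2 siRNA replicate 2 (0.0487), with equal array medians (0.0426), and with the mean (0.0377) or the most variable (0.0339) of a gene's probe sets. Of 17 genes of purine and one-carbon synthesis 10 fell and 0 rose, 10 and 0 adjusted over the list alone. SHMT2 fell about 2-fold (adjusted p = 1.34e-09), and PPAT (-0.93), ADSL (-0.86) and MTHFD2 (-0.61) fell too, with list adjusted p = 0.00276 and adjusted p = 0.355 with an estimated correlation. Of the conjugating enzymes, 9 of 21 glutathione S-transferases and UGTs fell and 1 rose, 9 and 1 adjusted over the list alone. GSTP1 was at -0.63, MGST1 at -0.52 and MGST2 at 0.63 (list adjusted p = 0.134; adjusted p = 0.381 with an estimated correlation). This list passed with the mean of a gene's probe sets (adjusted p = 0.0311) and with the most variable one (0.0442). In the list of NRF2 and its regulators 10 of 15 fell and 2 rose, 10 and 3 adjusted over the list alone. That list holds the siRNA target NFE2L2 itself and NFE2L3, which differed from mock by -0.05 only. The autophagy receptor SQSTM1 was at -1.40 and the small MAF partner MAFG at -1.11 (adjusted p = 0.0238; adjusted p = 0.319 with an estimated correlation).

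Genes of protein turnover and growth moved as well. Of 28 proteasome genes 24 fell and 1 rose, 26 and 1 adjusted over the list alone. PSMD12 was at -0.95 (1 of 2 probe sets with that sign), PSMB5 at -0.89 and PSMC3 at -0.69 (adjusted p = 1.70e-08; adjusted p = 0.327 with an estimated correlation). Of 26 DNA replication genes 20 fell and 1 rose, 21 and 1 adjusted over the list alone. The ribonucleotide reductase subunit RRM2 was at -0.84, MCM10 at -0.77 and CDC45 at -0.75 (adjusted p = 1.67e-06; adjusted p = 0.319 with an estimated correlation). Of 27 mitosis genes 15 fell and 3 rose, 15 and 3 adjusted over the list alone. CCNA2 (-0.73), CDC20 (-0.61) and CCNB1 (-0.56) fell, with adjusted p = 0.0448 for the list and adjusted p = 0.69 with an estimated correlation. The mitosis list passed in 8 of 16 alternative settings (adjusted p from 0.01 to 0.168) and was lost without NS siRNA replicate 1 (0.061) or 2 (0.069), Nrf2 siRNA replicate 1 (0.104) or 3 (0.059), or mock replicate 2 (0.0523). It was also lost with the mean (0.0828) or the most variable (0.168) of a gene's probe sets and in a fit of 2 groups only (adjusted p = 0.0562). Of 19 unfolded protein response genes 16 rose and 0 fell, 17 and 0 adjusted over the list alone. The stress sensors ERN1 and EIF2AK3 were at 1.59 and 1.17 and the ER-associated degradation gene HERPUD1 at 0.82 (adjusted p = 7.66e-09; adjusted p = 0.157 with an estimated correlation). Of the 3 probe sets of ERN1, 1 was called in the other direction, and 1 of 2 probe sets of EIF2AK3 had the sign given. Of 18 cholesterol synthesis genes 13 rose and 2 fell, 13 and 2 adjusted over the list alone. STARD4 was at 1.15, TM7SF2 at 1.02 and HSD17B7 at 0.44 (adjusted p = 0.000111; adjusted p = 0.319 with an estimated correlation). Of 10 fibroblast marker genes 4 rose and 0 fell, 4 and 0 adjusted over the list alone. LUM rose by 3.01, COL3A1 by 1.73, COL1A1 by 1.12 and THY1 by 0.34, with 3 of 5 probe sets of COL3A1 and 3 of 5 of COL1A1 going that way, while COL1A2 differed by 0.00 ± 0.06 (SE) and DCN by -0.06 ± 0.04 (list adjusted p = 0.039; adjusted p = 0.319 with an estimated correlation; median over the list 0.014). Without Nrf2 siRNA replicate 1 the fibroblast list had adjusted p = 0.051, and with the mean of a gene's probe sets 0.0651. In all, 13 of 32 lists passed, 3 higher and 10 lower; with an estimated correlation between genes 0 passed, so the list calls rest on the preset correlation of 0.01.

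**Figure D2:**
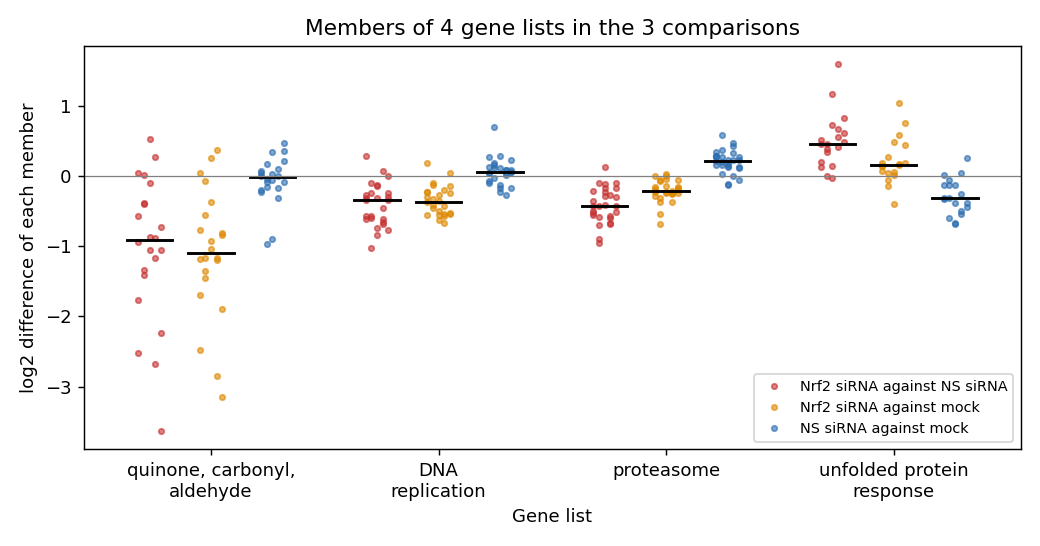
Difference (log2) of each measured member of 4 gene lists, 1 point per gene, in the 3 comparisons, with the median of each list as a black bar. The median of the proteasome list was -0.429 against NS siRNA and -0.216 against mock, and NS siRNA itself lay 0.218 above mock; the unfolded protein response list ran the other way, with medians of 0.454, 0.148 and -0.313.

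The comparison of Nrf2 siRNA with mock used the second control. CPLX2, the complexin, fell 11.4-fold, CYP4F11 8.90-fold, F2RL2 8.34-fold, ALDH3A1 7.19-fold and NMRAL2P 6.14-fold. The largest rises were those of the integrin ITGB8 (3.23 ± 0.06 SE, log2), the selenium transport protein gene SELENOP (3.06 ± 0.09), IL33 (2.90), EHF (2.78) and TOX3 (2.72). For ITGB8 2 of 5 probe sets and for SELENOP 2 of 3 had the same sign against mock. ITGB8 (5.27), SELENOP (4.98), IL33 (5.38) and TOX3 (6.83) lay below the array medians in mock, so these folds and their ranks are uncertain. Of 22 quinone, carbonyl and aldehyde genes 18 fell and 2 rose, 18 and 2 adjusted over the list alone (adjusted p = 8.86e-15; adjusted p = 0.113 with an estimated correlation), and 10 of 16 glutathione genes fell and 1 rose, 10 and 1 adjusted over the list alone, with SLC7A11 at -2.62 (adjusted p = 8.65e-06; adjusted p = 0.127 with an estimated correlation).

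Other lists in that comparison held the following. The proteasome list fell in 21 of 28 members with 0 rising, 21 and 0 adjusted over the list alone (adjusted p = 1.17e-06; adjusted p = 0.29 with an estimated correlation), and DNA replication in 22 of 26 with 1 rising, 23 and 1 adjusted over the list alone (adjusted p = 2.20e-09; adjusted p = 0.127 with an estimated correlation). Of 18 p53 target genes 15 rose and 2 fell, 15 and 2 adjusted over the list alone. The death receptor FAS was at 1.01 and TP53INP1 at 0.77, whereas the pro-apoptotic gene BAX was at -0.49 (adjusted p = 3.94e-07; adjusted p = 0.127 with an estimated correlation). The p53 list did not pass against NS siRNA (camera adjusted p = 0.441), and 12 of its 18 genes rose in NS siRNA against mock as well. Of 17 epithelial genes 9 rose and 1 fell, 10 and 2 adjusted over the list alone. The keratin KRT19 was at 1.95, EPCAM at 1.20 and CDH1, E-cadherin, at 0.94 (adjusted p = 0.00015; adjusted p = 0.113 with an estimated correlation). The epithelial list did not pass against NS siRNA either (camera adjusted p = 0.165), and 6 of its 17 genes rose in NS siRNA against mock. The unfolded protein response genes rose in 11 of 19 and fell in 2, 12 and 2 adjusted over the list alone, with ERN1 at 1.04 (adjusted p = 0.00049; adjusted p = 0.127 with an estimated correlation), and 11 of 18 cholesterol synthesis genes rose and 0 fell, 11 and 0 adjusted over the list alone (adjusted p = 4.04e-05; adjusted p = 0.127 with an estimated correlation). Of the 10 fibroblast markers 3 rose and 0 fell, 3 and 0 adjusted over the list alone, with LUM at 2.31 and COL3A1 at 0.99 (adjusted p = 0.0294; adjusted p = 0.181 with an estimated correlation).

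The list calls against the 2 controls were not all the same, and no test compared the lists between controls. The list of NRF2 and its regulators, past the threshold against NS siRNA, did not pass against mock, with 6 of 15 members lower and 5 higher, 6 and 5 adjusted over the list alone (adjusted p = 0.183). Against mock, and not against NS siRNA, the pentose phosphate and NADPH list passed, with 8 of 14 members falling and 3 rising, 8 and 3 adjusted over the list alone, and ME1 at -1.75 (adjusted p = 0.0083; adjusted p = 0.181 with an estimated correlation). The same held for glutathione S-transferases and UGTs, where 11 of 21 fell and 1 rose, 12 and 1 adjusted over the list alone, with MGST1 at -0.78 (adjusted p = 0.00288; adjusted p = 0.127 with an estimated correlation). It held for glycolysis, where 10 of 19 fell and 1 rose, 11 and 1 adjusted over the list alone, with PFKP at -0.85 (adjusted p = 0.00207; adjusted p = 0.127 with an estimated correlation). In oxidative phosphorylation 7 of 24 fell and 0 rose, 7 and 0 adjusted over the list alone, with CYC1 at -0.45 (adjusted p = 0.0126; adjusted p = 0.453 with an estimated correlation). In hypoxia 8 of 17 fell and 2 rose, 10 and 2 adjusted over the list alone, with ANGPTL4 at -0.96 (adjusted p = 0.0242; adjusted p = 0.361 with an estimated correlation). Of 31 interferon genes 10 rose and 4 fell, 11 and 4 adjusted over the list alone, with OAS1 at 0.64 (adjusted p = 0.0325; adjusted p = 0.174 with an estimated correlation). Lists that passed against both controls included heme and iron, with 9 of 12 down and 2 up, 9 and 2 adjusted over the list alone (adjusted p = 4.04e-05; adjusted p = 0.127 with an estimated correlation), and purine and one-carbon synthesis, with 12 of 17 down and 0 up, 12 and 0 adjusted over the list alone (adjusted p = 6.99e-05; adjusted p = 0.178 with an estimated correlation). Of 27 mitosis genes 13 fell and 0 rose, 14 and 0 adjusted over the list alone (adjusted p = 0.000106; adjusted p = 0.346 with an estimated correlation). Thioredoxin and peroxiredoxin genes fell in 5 of 11 with 0 rising, 6 and 0 adjusted over the list alone (adjusted p = 0.000555; adjusted p = 0.127 with an estimated correlation), and ABC efflux transporters in 6 of 9 with 2 rising, 6 and 2 adjusted over the list alone (adjusted p = 0.00534; adjusted p = 0.158 with an estimated correlation). In all, 20 of 32 lists passed against mock, and 0 with an estimated correlation.

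The whole comparison called 6530 genes, 3234 higher and 3296 lower, with 285 at 2-fold or more, 203 higher and 82 lower. That was 33% of genes. NS siRNA against mock, with no NRF2 target, called nearly as many (6082 genes, 30.8%), with 177 at 2-fold or more, so the total cannot be read as an NRF2 effect.

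Against both controls, HMOX1 differed by -2.61 (log2) from NS siRNA and by -2.53 from mock. The pair of values was -2.52 and -2.48 for PTGR1, -2.35 and -2.38 for TRIM16, and -2.24 and -2.06 for GCLM. IL33 rose by 3.16 and 2.90 and the prostaglandin synthase PTGS2 by 1.53 and 1.55. A fall against one control and not the other was seen for NFE2L3, an NRF2 relative, at -1.91 against NS siRNA and -0.05 against mock. In total 4947 genes were called the same way in both comparisons, 2496 higher and 2451 lower, and 351 in opposite ways. By 2-fold or more against both, 153 were higher and 57 lower. Independent lists of these sizes would share 680 higher and 878 lower genes. The covariance of the differences was 0.0848, against 0.00177 in simulated unchanged groups that share the Nrf2 siRNA arrays. Part of the overlap may come from those 3 shared arrays, which are too few to split.

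**Figure D3:**
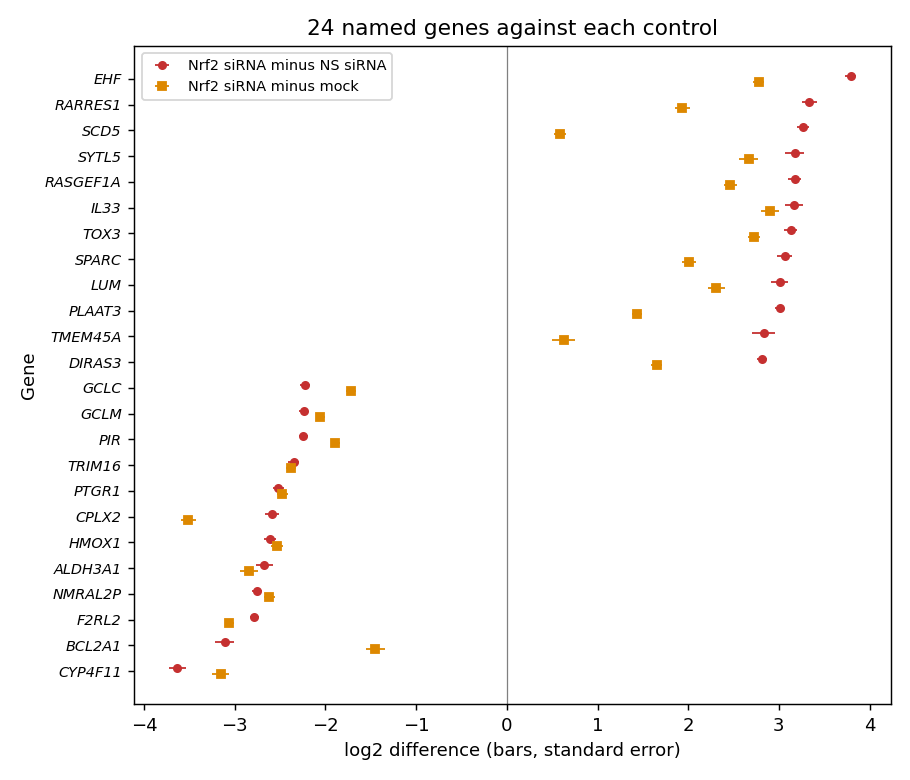
Difference (log2, with its standard error) of the 24 named genes with the 12 largest falls and the 12 largest rises, for Nrf2 siRNA minus NS siRNA and Nrf2 siRNA minus mock. CYP4F11 fell the most against NS siRNA (-3.63), and SCD5 rose by 3.27 against NS siRNA but by 0.58 against mock.

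Against the mean of both controls, 8589 genes passed, 4034 higher and 4555 lower, with 329 at 2-fold or more, 240 higher and 89 lower.

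NS siRNA against mock compares the 2 controls. The adhesion gene CEACAM6 was 2.45 ± 0.08 (SE, log2) higher after NS siRNA, the pentraxin PTX3 2.09, RRAD 2.08, COXFA4L3 1.93, NFE2L3 1.86, the BMP antagonist GREM1 1.83, the protease MMP7 1.72, BCL2A1 1.66, IRAK2 1.65 and the AP-1 gene FOSL1 1.64. SCD5 fell the most (-2.68 ± 0.06), followed by NPTX1 (-2.49), IGFBP7 (-2.31), TMEM45A (-2.20), TMCO1 (-2.10), MSC-AS1 (-1.91), TNS1 (-1.91), APLP2 (-1.89), GLIPR1 (-1.85) and HTRA1 (-1.79). SCD5, TMEM45A and MSC-AS1 in NS siRNA lay below the array medians, as did PTX3, RRAD and GREM1 in mock. The size and rank of the differences of these genes are therefore uncertain. For SCD5 1 of the 4 probe sets was called in the opposite direction. In the mesenchymal and TGF-beta list 12 of 26 members fell and 7 rose, 13 and 8 adjusted over the list alone. The ligand TGFB1 was at -1.49, the receptors TGFBR1 at -1.43 and TGFBR2 at -0.85, and the gelatinase MMP2 at -1.29 (list adjusted p = 0.0486, and adjusted p = 0.657 with an estimated correlation). For MMP2 1 of 3 probe sets had that sign.

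Lists moved between the 2 controls as well. Of 28 proteasome genes 21 rose and 0 fell after NS siRNA, 22 and 2 adjusted over the list alone (adjusted p = 1.11e-05; adjusted p = 0.657 with an estimated correlation), and 14 of 19 unfolded protein response genes fell and 1 rose, 15 and 1 adjusted over the list alone (adjusted p = 2.73e-07; adjusted p = 0.244 with an estimated correlation). Of 22 inflammatory and NF-kB genes 13 rose and 1 fell, 14 and 1 adjusted over the list alone. NFKB2 was at 0.76 and TNFAIP3 at 0.58 (adjusted p = 0.000191; adjusted p = 0.356 with an estimated correlation). Of 18 p53 targets 12 rose and 2 fell, 12 and 2 adjusted over the list alone. BAX was at 0.62 and FAS at 0.55, whereas CCNG1 was at -0.87 (adjusted p = 0.000215; adjusted p = 0.496 with an estimated correlation). Of 17 epithelial genes 6 rose and 1 fell, 6 and 1 adjusted over the list alone. CLDN1 was at 1.06 and KRT19 at 0.80 (adjusted p = 0.0234; adjusted p = 0.356 with an estimated correlation). The list of NRF2 regulators rose in 8 of 15 and fell in 3, 8 and 3 adjusted over the list alone, with NFE2L3 and BACH1 (0.66) among the risers (adjusted p = 0.027; adjusted p = 0.496 with an estimated correlation). Fibroblast markers LUM (-0.70), COL3A1 (-0.74) and COL1A1 (-0.94) were lower, 3 of 10, with 0 higher, 3 and 0 adjusted over the list alone, and the list did not pass (adjusted p = 0.158, and adjusted p = 0.657 with an estimated correlation). For COL1A1 1 of 5 probe sets was called in the opposite direction, and for COL3A1 3 of 5 had the sign given. The comparison called 6082 genes, 3083 higher and 2999 lower. That near balance depends on the scaling, with 2369 higher and 3205 lower at equal array medians, and 3507 and 2874 with quantile normalization. The comparison had 177 at 2-fold or more, 43 higher and 134 lower. With the mean of all probe sets of a gene, 103 genes reached 2-fold. Of the 4156 genes higher in Nrf2 siRNA than in NS siRNA, 2285 (55.0%) were called lower in NS siRNA than in mock, and of the 5266 lower ones 2157 (41.0%) were called higher there. Independent lists of these sizes would share 630 and 821 genes. The 2 comparisons share the NS siRNA arrays with opposite sign. The covariance of their differences was -0.0608, against -0.00179 in simulated unchanged groups with that sharing.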

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

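The tests of a shared siRNA response, of interferon, of array scaling and of fibroblasts, the matched-brightness test and the counts of splits were chosen after the result was seen; the test of signal compression over all bright genes was set before its result, though after single examples had been seen.

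Probe sets outside the comparisons carried signal too. Of 11721 probe sets with no gene name here, 2380 were called in Nrf2 siRNA against NS siRNA, 58 higher and 21 lower by 2-fold or more, against 1133 called in NS siRNA against mock. Of 1801 probe sets that match several genes, 754 were called, with 24 higher and 8 lower by 2-fold or more; the one shared by AKR1C1 and AKR1C2 was at -2.16 ± 0.08 (SE, log2).

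NS siRNA and mock, both controls, differed in 6082 genes. A response to siRNA transfection shared by both siRNAs was examined in the 134 genes lower by 2-fold or more in NS siRNA. The median ratio of the difference in Nrf2 siRNA against mock to that in NS siRNA against mock was -0.021 (quartiles -0.27 and 0.21). So most of these genes did not stay lower in Nrf2 siRNA: 44 were called lower there and 53 higher. A shared fall that the Nrf2 siRNA offset would give the same ratio, so the test cannot exclude a shared response. For the 43 genes higher in NS siRNA a shared response stays open too, with a median ratio of 0.127 (quartiles -0.09 and 0.57). Of these, 21 were also higher in Nrf2 siRNA and 8 lower. CEACAM6 (2.45 and 2.03) and MMP7 (1.72 and 2.23) were higher with both siRNAs. The p53 and epithelial lists passed upward with both, but not with an estimated correlation (adjusted p = 0.127 and 0.496 for p53, 0.113 and 0.356 for epithelial), and both comparisons share the mock arrays. Over all genes the covariance of the 2 differences was 0.00128 against 0.00178 in simulated unchanged groups. In both comparisons 773 genes were higher and 760 lower, where independent lists of these sizes would share 504 and 500. Opposite ways went 1008 genes (higher in Nrf2 siRNA, lower in NS siRNA) and 812 (the reverse), where independent lists would share 490 and 514. An interferon response still present at 96 h is argued against: 0 of 31 interferon genes rose by 1.5-fold or more. The highest was IRF7 at 0.43 and the list median was 0.017, with 6 members called higher and 8 lower. No earlier time was sampled, so a response that had ended by 96 h was not tested. For scaling of the arrays, 5574 genes were still called with array medians set equal. The medians already lay between 7.51 and 7.57, so that test could change little and does not decide the question. Quantile normalization, which gives all arrays the same distribution, left 6381 genes called. RMA already includes normalization between arrays, so this test could change little too and does not decide the question either. An off-target effect of the NS siRNA, whose sequence is not given in the sources used here, and separate handling of each group of cultures stay open, and the design cannot tell them apart. A candidate to follow, picked after the values were seen, is the fall of TGFB1 (-1.49), TGFBR1 (-1.43) and TGFBR2 (-0.85) together with SPARC (-1.05) and IGFBP7 (-2.31). SPARC and IGFBP7 are not in the mesenchymal and TGF-beta list. In that list 12 of 26 members were lower and 7 higher, and camera with an estimated correlation did not pass (adjusted p = 0.657).

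Among NRF2 targets with bright signals, NQO1, at 14.48 in NS siRNA, differed by -0.88 between Nrf2 siRNA and NS siRNA, while TXNRD1, at 14.08, differed by -1.72, SRXN1, at 13.47, by -1.95 and TRIM16, at 13.27, by -2.35, so small folds are not a rule of bright genes. Signal compression near the top of the scale may lower single folds such as that of NQO1. The test took genes changed the same way against both controls. For 28 of 53 genes (52.8%) whose brightest probe set averaged 13 or more, a dimmer probe set showed a larger change of the same sign. That held for 167 of 964 genes (17.3%) whose brightest averaged 9 to 11 (exact Fisher test, two-sided, p = 1.58e-08). With dimmer probe sets of similar brightness (8 to 10) the shares were 9 of 16 and 123 of 577 (exact Fisher p = 0.00285). The shares at 13 or more are near even, as they would be if both probe sets responded alike. The small p values therefore rest on the low shares at 9 to 11, and the test does not by itself show compression. A larger change counted whatever its margin, as for HUWE1 (0.18 and 0.20). Examples are TKT at -0.69 and -1.99 on the bright and the dimmer probe set, SQSTM1 at -1.40 and -2.39, AKR1C1 at -1.06 and -2.23, and NQO1 at -0.88 and -1.38; PGD (-0.74 and -0.22), TXN (-0.94 and -0.68) and AKR1C2 (-1.17 and -1.09) went the other way. Probe sets that read different transcript variants or paralogs stay open as a further cause, untested here.

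LUM, COL3A1, COL1A1 and THY1, taken as fibroblast markers, were higher after Nrf2 siRNA than after NS siRNA. RNA from fibroblasts in the Nrf2 siRNA cultures would raise the whole list. In 7 of its 10 measured markers the difference plus 2 SE lay below 0.5 (log2). Of these, PDGFRA, PDGFRB, POSTN and FAP lay below the array medians in every group, where a rise can be understated. THY1 (0.34 ± 0.06) was itself called higher. The argument against fibroblast RNA therefore rests on COL1A2 (0.00 ± 0.06, at 7.64 in NS siRNA, near the medians) and DCN (-0.06 ± 0.04, at 8.18), both abundant in fibroblasts. The labels name a cell line and no sort. A change within the A549 cells following NRF2 loss, and the lower levels after NS siRNA than in mock of COL1A1 (-0.94), COL3A1 (-0.74) and LUM (-0.70), stay as hypotheses, since the genes were found and tested on the same arrays. Against mock, COL1A1 differed by 0.18 and did not pass (limma adjusted p = 0.176), so its rise was seen against NS siRNA only. LUM (2.31) and COL3A1 (0.99) rose against mock too, so the lower NS siRNA levels are not the whole of their rise. The probe sets of COL1A1 and of COL3A1 did not all go the same way between NS siRNA and mock.

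Chance was examined by regrouping the arrays. For 3 against 3 arrays only 10 splits exist, too few for a share under 0.05: the real split gave 9422 genes in Nrf2 siRNA against NS siRNA, 6530 against mock and 6082 in NS siRNA against mock, and 559, 285 and 177 at 2-fold or more, in each case 1 of 10 splits, with 0 genes as the highest of the others. For the gene lists 2 of 10 splits gave as many as the real 13, the highest other being 13. For Nrf2 siRNA against the mean of both controls, in a fit of 3 against 6 arrays, 1 of 84 splits gave as many as the real 5548 genes; the highest other, 4757, was the split that set the 3 NS siRNA arrays apart, which is a structure of the samples and not chance. For genes changed the same way against both controls, 1 of 100 splits gave as many as 4947, the highest other, 3407, being a split that kept the 3 Nrf2 siRNA arrays together and mixed the controls, which again follows the samples' structure. These last 2 results argue against a random assignment of single arrays, each share being the smallest possible. They cannot tell an effect of the siRNA from separate handling of each group of cultures.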

How the results depend on the processing

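Under the alternatives run for each, the 8 counts of genes, the count of lists and the NFE2L2 level stayed within 1.5 times their value, or on the same side of the threshold, except the following; the RNA ratio was run under the 2 other scalings only, and lists not under single probe sets, the eBayes trend, the 0.01 threshold or the unmoderated test. Tested one by one, 41091 probe sets gave 17148 calls in Nrf2 siRNA against NS siRNA (1056 at 2-fold), 11744 against mock (546), 10648 in NS siRNA against mock (330), 15792 against the mean of both controls and 8741 the same way against both, by construction from more tests. The mean of a gene's probe sets gave 103 genes at 2-fold in NS siRNA against mock instead of 177. Lists past the threshold numbered 13 in the main setting, 26 with fry and 0 with an estimated correlation. GATA6 went from 0.21 to -0.20 with the probe set of largest interquartile range; the cause was not tested. NFE2L2 was at -1.03 with the mean of its probe sets. Without single arrays the counts ran from 8173 to 9382, 5581 to 6471 and 5069 to 6172 in the 3 pairwise comparisons, and NFE2L2 from -1.88 to -1.78. Of 2997 values of 167 named results, 2975 kept direction and call, 21 lost the call (RPS9, CD74, GATA6, CDH5 and SFTPC) and 1 reversed. Of 510 list values, all in Nrf2 siRNA against NS siRNA, 493 kept theirs, 10 were lost (mitosis and fibroblast) and 7 gained. List calls in the comparisons with mock were rerun only with an estimated correlation and with fry, under none of the other alternatives. With the replicate block, counts were 9720, 6804 and 6366; 5 of 9 same-numbered pairs of arrays correlated above 0.1 in their deviations, from -0.208 to 0.231, and 7 of 9 arrays correlated best with an array of their own number, a hint from the data and not from the design, so the numbers were not taken as pairs. Signal over background is unknown without detection calls; with genes above the median level of all probe sets, 13139 genes tested gave 8329 calls against NS siRNA.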

Other observations

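The lists below did not pass in Nrf2 siRNA against NS siRNA, though single members changed. Of all genes 47.6% were called in that comparison, so called members alone say nothing particular about a list. In autophagy and lysosome the phosphoinositide-binding gene WIPI1 rose by 2.62 (log2) and MAP1LC3B by 1.15, while the galactosidase GLA was at -1.08 and SQSTM1 at -1.40; 6 of 19 rose and 10 fell, 6 and 10 adjusted over the list alone (adjusted p = 0.803). Compared with mock, NS siRNA arrays had WIPI1 at -1.57 and MAP1LC3B at -1.01. Among inflammatory genes NFKB2 was at -1.50 and TNFAIP3 at -0.75, whereas PTGS2 and CXCL1 rose by 1.53 and 0.79. In that list 4 of 22 rose and 11 fell, 4 and 12 adjusted over the list alone (adjusted p = 0.159). Against mock NFKB2 was at -0.74, PTGS2 at 1.55 and CXCL1 at 0.935, while TNFAIP3 at -0.17 did not pass (adjusted p = 0.0913). In the mesenchymal and TGF-beta list 11 of 26 rose and 8 fell, 11 and 9 adjusted over the list alone, with TGFBR2 at 1.93 and MMP2 at 1.42, for which 1 of 3 probe sets had that sign (adjusted p = 0.232). Against mock TGFBR2 was at 1.08, while MMP2 at 0.125 did not pass (adjusted p = 0.214). In that comparison 7 members of the list rose and 9 fell. Of 17 epithelial genes 7 rose and 4 fell, 7 and 4 adjusted over the list alone, with KRT19 at 1.15 (adjusted p = 0.165). Interferon genes were mixed, 9 of 31 rising, OAS1 by 1.38 and IRF9 by 0.76, and 5 falling, 9 and 5 adjusted over the list alone (adjusted p = 0.185). Of 18 p53 targets 8 rose and 6 fell, 8 and 6 adjusted over the list alone, with CCNG1 at 1.14 and BAX at -1.11 (adjusted p = 0.441).

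The phosphofructokinase PFKP was at -1.13 and the glucose transporters SLC2A3 and SLC2A1 at 0.75 and -0.49; 8 of 19 glycolysis genes fell and 2 rose, 9 and 2 adjusted over the list alone (adjusted p = 0.363). Respiratory chain genes fell in 11 of 24 and rose in 3, 11 and 3 adjusted over the list alone, with CYC1 at -0.50 (adjusted p = 0.343). Fatty acid oxidation had 6 of 17 down and 5 up, 6 and 5 adjusted over the list alone, with ACADM at -0.55 (adjusted p = 0.916), and fatty acid synthesis 7 of 16 down and 5 up, 7 and 5 adjusted over the list alone, with FASN at -0.59 (adjusted p = 0.944). Hypoxia genes fell in 9 of 17 and rose in 5, 10 and 6 adjusted over the list alone, with ADM at -1.04, although ADM stood at 0.01 against mock (adjusted p = 0.449). ATF4 targets fell in 11 of 21 and rose in 4, 12 and 5 adjusted over the list alone, with CEBPB and ASNS both at -1.01 and NUPR1 at 0.89 (adjusted p = 0.185). Ribosomal protein genes rose in 2 of 17 and fell in 0, 2 and 0 adjusted over the list alone (adjusted p = 0.448). RNA interference genes rose in 4 of 12 and fell in 2, 4 and 2 adjusted over the list alone, with AGO2 at -0.64 (adjusted p = 0.715).

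Of 8 immune markers 1 rose, the monocyte receptor CD14 by 0.96, and 1 fell, 1 and 1 adjusted over the list alone (adjusted p = 0.943). Of 9 endothelial markers 1 rose and 1 fell, 0 and 1 adjusted over the list alone, with TIE1 at -0.35 (adjusted p = 0.668). Of 16 lung alveolar and airway markers 4 rose and 2 fell, 4 and 1 adjusted over the list alone, with the surfactant lipid transporter ABCA3 at 0.82 and the pioneer factor FOXA1 at 0.80 (adjusted p = 0.39).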
